A study of Homo sapiens with 14 samples.

How the data were processed

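Primary human erythroid progenitor cells, grown from CD34-selected blood-forming cells in erythroid medium, were infected with lentiviruses carrying short hairpin RNAs (shRNAs), per the labels' protocols. RNA from each sample was amplified linearly, labelled with biotin as cRNA and hybridised to 1 oligonucleotide array per sample, per the labels' protocols. The 14 arrays fall into 5 groups named in the labels: a luciferase control shRNA (n = 3), the HDAC1 shRNAs A3 (n = 2) and G10 (n = 3), and the HDAC2 shRNAs B10 (n = 3) and H6 (n = 3). The titles number the HDAC1 A3 replicates 1 and 3, and a replicate 2 of that group was not analysed here.

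The values used are intensities that the authors deposited as 1 number per probe set and array. Per the submitters' processing notes they were made with RMA (robust multi-array average), which corrects background, normalizes between arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here. The deposited intensities are on a linear scale, with array medians between 55.88 and 61.42 and array maxima between 9062 and 9935. RMA compresses differences near the bottom and the top of the scale, so fold changes of very dim and of very bright transcripts can be understated.

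The intensities were taken to log2. Of 22277 probe sets, 62 were control probe sets and were left out. Of the others, 19730 were listed for 1 gene, 568 for several genes and 1923 were not listed in the probe annotation used here. Probe sets listed for several genes were left out, except that those listed for exactly HBG1 and HBG2, or for exactly HBA1 and HBA2, were kept as the units HBG1/HBG2 and HBA1/HBA2. A further 51 probe sets of sex-linked marker genes were left out of every table. This left 12145 genes. For the 4499 genes with several probe sets, the probe set with the highest mean over all 14 arrays stood for the gene. Where several probe sets of a gene passed the test, they had opposite signs for 6 of 391 genes with the HDAC1 shRNAs, 14 of 608 with the HDAC2 shRNAs and 3 of 305 between them. Gene symbols are those of the array annotation and no symbol needed an update. No genome was used here, so no coordinates are given.

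Differential expression was tested with limma 3.58.1 in R 4.3.3. All 14 arrays entered 1 linear model with a mean per shRNA group, followed by empirical Bayes moderation with default settings (9 residual and 3.81 prior degrees of freedom). The HDAC1 effect is the mean of the A3 and G10 groups minus luciferase, each hairpin weighted equally, and the HDAC2 effect is built in the same way from B10 and H6. Further contrasts compared the HDAC1 with the HDAC2 shRNAs, each hairpin with luciferase, and the hairpins of a target with each other. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Adjusted p-values of single genes are from this limma fit throughout. Changes are given as log2 fold with their standard error (SE), and the median log2 fold over all genes lay between -0.036 and 0.03 in the 9 contrasts.

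Of 23 gene lists with 467 genes, 410 genes were measured. Each list was tested with camera at a preset correlation between genes of 0.01, with adjustment over the 23 lists, and again with a correlation estimated for each list. Camera asks whether the genes of a list moved more than the other genes. Fry, an alternative, asks whether the genes of a list moved one way on balance and does not compare them with other genes. For every list, members that passed were counted over all genes tested and adjusted over the list alone. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names HDAC1, HDAC2, the globins, BCL11A, KLF1, GATA1, MYB, TAL1 and CDKN1A in each main comparison. It also names the 10 largest rises and the 10 largest falls for each target among genes that passed with the same sign for both hairpins, and the 5 and 5 largest between the targets. Up to 4 members of each list that passed, by size, and up to 3 rising and 3 falling genes for each hairpin and each pair of hairpins complete it. Genes outside the rule are said to have been chosen after their values were seen.

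The limma step was tested on simulated data with 12145 genes, of which 200 were changed by known amounts, 50 at each size. At log2 changes of 0.3, 0.6, 1.2 and 2 it recovered 46%, 80%, 100% and 98% of the changed genes for the HDAC1 comparison. The HDAC2 comparison recovered 44%, 82%, 100% and 100%, and HDAC1 against HDAC2 recovered 66%, 100%, 100% and 100%. False calls were 2.4%, 4.7% and 5.2% of all calls. The simulation gave all hairpins of a target the same change, so these rates do not cover differences between hairpins or effects of a single hairpin. The number of arrays limits the precision.

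Because the 4 hairpin groups share the luciferase arrays, unchanged groups were simulated 100 times against the same controls to show the correlation and covariance that shared controls give. The 3 luciferase arrays could not be divided into parts of 2. The alternatives tried were quantile normalization of the deposited values, centring of each array on its median, leaving out the dimmest genes, the mean of all probe sets of a gene, each probe set by itself, a trended and robust variance prior, array weights, a fit of only the groups compared, pooling of the hairpins of a target, the replicate number as a block, leaving out each array in turn, a minimum log2 fold of 1, Spearman correlation, the estimated correlation, fry, and lists without genes held by a second list. A fit without luciferase replicate 3 and HDAC2 H6 replicate 3 was added after the data had been seen. No 2 arrays held identical values.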

Results

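Gene expression was measured on 14 arrays of primary human erythroid progenitor cells that carried a short hairpin RNA (shRNA) from a lentivirus. A hairpin against luciferase, which human cells do not make, served as the control (n = 3). HDAC1, a histone deacetylase, was targeted by the hairpins A3 (n = 2) and G10 (n = 3), and its close relative HDAC2 by B10 (n = 3) and H6 (n = 3). The study asked whether loss of either enzyme changes the expression of fetal globin. Values are log2 of the deposited intensity, given as mean ± SD for groups and as log2 fold ± SE for contrasts, with adjusted p-values from limma. Array medians lay between 55.88 and 61.42 intensity units. The lowest correlation of each array with a replicate of its group was r = 0.9937 to 0.9975 across genes. The excess of 3' over 5' beta-actin signal, a sign of RNA length, was 1.89 ± 0.18 in luciferase, 1.72 ± 0.13 in A3, 1.74 ± 0.06 in G10, 1.6 ± 0.1 in B10 and 1.72 ± 0.18 in H6 arrays on the log2 scale. The same excess for GAPDH ran from 0.72 to 0.8. The number of arrays limits the precision. The labels call the samples biological replicates without naming separate cultures or donors, so the p-values measure only the spread between these samples.

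HDAC1 mRNA was lower in every array with an HDAC1 hairpin, and HDAC2 mRNA in every array with an HDAC2 hairpin, than in any luciferase array. HDAC1 read 10.06, 10.07 and 10.12 in the luciferase arrays, 9.36 and 9.05 with A3, 8.63, 8.43 and 8.52 with G10, 9.67, 9.69 and 9.74 with B10, and 9.96, 9.95 and 9.95 with H6. HDAC2 read 11.5, 11.62 and 11.57 in the luciferase arrays, 11.53 and 11.44 with A3, 11.58, 11.51 and 11.47 with G10, 10.59, 10.75 and 10.54 with B10, and 10.95, 10.93 and 10.99 with H6. HDAC1 fell 2.33-fold with the HDAC1 hairpins (log2 fold -1.22 ± 0.07 SE, adjusted p = 2.96e-07, 5 of 5 arrays). G10 lowered it more than A3, with log2 folds of -1.56 and -0.88 and a difference of 0.68 ± 0.09 (adjusted p = 0.000199). HDAC2 fell 1.71-fold with the HDAC2 hairpins (-0.77 ± 0.06, adjusted p = 2.62e-06, 6 of 6 arrays). B10 lowered HDAC2 more than H6, with -0.94 and -0.61 and a difference of -0.33 ± 0.07 (adjusted p = 0.00395). HDAC1 was also lower with the HDAC2 hairpins (-0.26 ± 0.07, adjusted p = 0.0154, 6 of 6 arrays), at -0.38 with B10 and -0.13 with H6. That call was lost without luciferase replicate 2 (adjusted p = 0.0517), without both luciferase replicate 3 and H6 replicate 3 (0.0657), a fit chosen after seeing the data, and with the hairpins pooled (0.385). HDAC2 did not pass with the HDAC1 hairpins (-0.06 ± 0.06, adjusted p = 0.587).

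**Figure D1:**
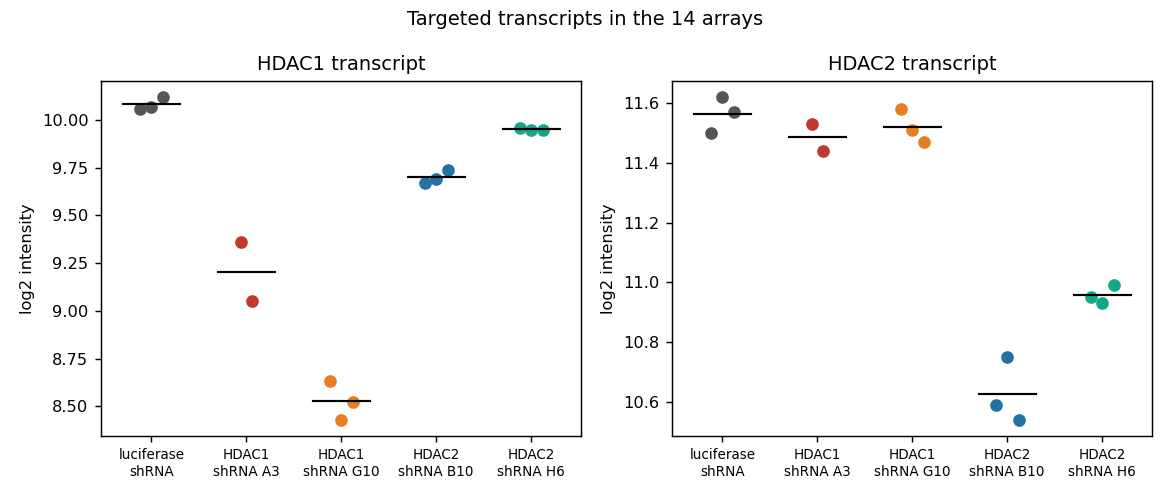
Log2 intensity of HDAC1 (left) and HDAC2 (right) in each of the 14 arrays, by hairpin, with 1 point per array and a line at each group mean. HDAC1 lay between 8.43 and 9.36 with its own hairpins and between 10.06 and 10.12 with luciferase, and HDAC2 between 10.54 and 10.99 with its own hairpins and between 11.5 and 11.62 with luciferase.

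The first comparison asked what knockdown of HDAC1 changed. HBE1, the embryonic beta-like globin, read 7.74 ± 0.29 (SD, n = 3) with luciferase and 10.77 ± 0.38 (SD, n = 5) over the HDAC1 arrays. It lay above every luciferase array in 5 of 5 arrays and rose 8.6-fold with A3 and G10 weighted equally (log2 fold 3.1 ± 0.14 SE, adjusted p = 5.84e-08). Its log2 fold was 3.44 with A3 and 2.76 with G10, although A3 lowered HDAC1 mRNA less. BCL11A, the repressor that silences fetal globin, fell 1.99-fold (-0.99 ± 0.1, adjusted p = 1.75e-05, 5 of 5 arrays). KLF1, the erythroid factor that drives adult globin and BCL11A, fell 1.21-fold (-0.28 ± 0.06, adjusted p = 0.00538, 5 of 5 arrays). Gamma-globin, the fetal beta-like globin read by probe sets shared by HBG1 and HBG2, was 1.11-fold higher, at 13.09 ± 0.03 against 12.94 ± 0.04, above every luciferase array in 5 of 5 arrays, and did not pass (0.15 ± 0.05, adjusted p = 0.0558). GATA1, MYB and TAL1, regulators of the erythroid lineage, did not pass either, with log2 folds of -0.18, -0.04 and 0.04 and adjusted p-values of 0.238, 0.747 and 0.718.

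Of the 7 globins measured, 2 rose and 2 fell with the HDAC1 hairpins, and adjusted over the list alone 3 rose and 3 fell. Beside HBE1, the adult delta-globin HBD rose (0.21 ± 0.06, adjusted p = 0.0292, beyond luciferase in 2 of 5 arrays), at 0.39 with A3 and 0.03 with G10. Alpha-globin, HBA1/HBA2, fell (-0.29 ± 0.09, adjusted p = 0.0407, 5 of 5) and beta-globin, HBB, fell (-0.17 ± 0.05, 0.0307, 5 of 5). These 3 calls were weak: of the 14 fits without 1 array, 6 lost HBD (highest adjusted p = 0.151, without luciferase replicate 2), 8 lost HBA1/HBA2 (0.17, without luciferase replicate 1) and 7 lost HBB (0.122, without luciferase replicate 2). HBD was also lost with arrays centred on their medians (0.0931), HBA1/HBA2 with quantile normalization (0.0832), and HBB with the mean of all probe sets (0.058). With only the groups compared, HBB (0.0648) and HBD (0.0731) were lost. For HBA1/HBA2, HBB and HBD, the replicate block ended all 3 calls (0.077, 0.0638 and 0.0585), as did pooled hairpins (0.606, 0.272 and 0.748). The alpha-like theta-globin HBQ1 and embryonic zeta-globin HBZ did not pass (-0.24, adjusted p = 0.0945, and -0.06, 0.81). The list as a whole did not pass camera (adjusted p = 0.443), and its median of -0.059 was opposite in sign to its mean of 0.386 and to the direction camera gave, which was up. Fry gave an adjusted p of 0.000229 for it. For gamma-globin, 3 alternatives of 10 passed: the mean of all its probe sets (0.18, adjusted p = 0.0107), leaving out the dimmest genes (0.0284) and a trended and robust prior (0.00116), within a range of 0.00116 to 0.255. Of its other probe sets, the first rose (0.26, adjusted p = 0.00349) and the second did not pass (0.13, 0.145). All lie near the brightest intensities of the arrays, where a change can be understated.

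**Figure D2:**
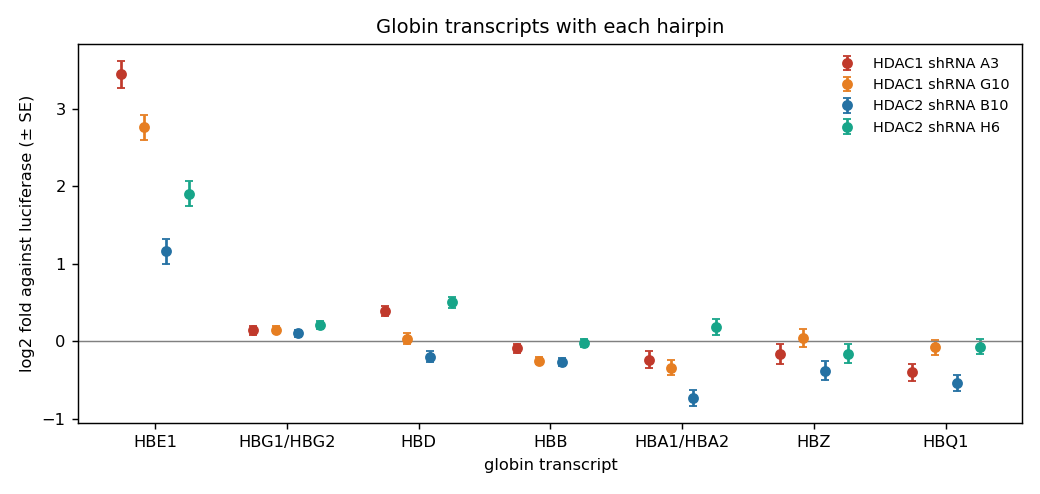
Log2 fold against luciferase of the 7 globins measured, for each of the 4 hairpins, with bars of 1 SE. HBE1 stands above the other globins with every hairpin, at 3.44 with A3, 2.76 with G10, 1.16 with B10 and 1.9 with H6, and HBG1/HBG2 lies between 0.1 and 0.21.

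In all, 1754 of 12145 genes changed with the HDAC1 hairpins, 989 higher and 765 lower, and 183 of them by at least 2-fold, 162 higher and 21 lower. The largest rises were in AXL, a receptor tyrosine kinase (log2 fold 3.44 ± 0.2, adjusted p = 3.64e-07), CALB1, a calcium-binding protein (3.28 ± 0.16, 9.22e-08), the cytokine IL24 (3.25 ± 0.42, 0.000151) and ALDH1A2, an enzyme of retinoic acid synthesis (3.2 ± 0.28, 6.56e-06). HBE1 and HEPH, a copper-dependent iron oxidase (3.01 ± 0.13, adjusted p = 4.69e-08), came next. SEPTIN10, PHLDA1, the chemokine CCL1 and CH25H, which makes 25-hydroxycholesterol, rose by 2.61, 2.6, 2.55 and 2.43 on the log2 scale. All 10 lay above every luciferase array in 5 of 5 arrays. The largest falls were in the beta-tubulin TUBB2B (-2.22 ± 0.22, adjusted p = 1.46e-05), JCHAIN, which links immunoglobulins, TNXB of the extracellular matrix (-1.52 ± 0.13, 6.56e-06), B3GALNT1, which makes the globoside of red cells (-1.48), and the steroid hydroxylase CYP21A2 (-1.39). SELENOP, PLXNC1, NYNRIN, CST7 and PVALB fell by 1.32, 1.29, 1.29, 1.28 and 1.26, and 8 of these 10 lay below every luciferase array in 5 of 5 arrays, with JCHAIN and SELENOP in 4. JCHAIN (-1.94 ± 0.57, adjusted p = 0.0363) read 3.19 higher in luciferase replicate 3 than in the other luciferase arrays, and without that array it fell by only 0.88 (adjusted p = 0.0178). Its call was lost without A3 replicate 1 (0.0908), A3 replicate 3 (0.0773), G10 replicate 1 (0.07) or G10 replicate 3 (0.0598). It was also lost with array weights (0.0544), a trended and robust prior (0.089), only the groups compared (0.0981) and pooled hairpins (0.234). TNXB and CYP21A2 each have a pseudogene copy that a probe set can also read.

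Erythroid genes were lower with the HDAC1 hairpins in 4 of the lists. Of 13 genes of heme synthesis and iron uptake, 8 fell and 0 rose, 9 and 0 adjusted over the list alone (camera adjusted p = 5.54e-06, adjusted p = 0.025 with an estimated correlation). ALAD, the enzyme that makes porphobilinogen, fell by 1.09 and the ferric reductase STEAP3 by 0.44. Of 19 genes of the red cell membrane and blood groups, 7 fell and 2 rose, as many adjusted over the list alone (camera adjusted p = 0.00757, adjusted p = 0.156 with an estimated correlation). The membrane skeleton protein ADD2 fell (-1.07 ± 0.1), as did the blood group genes KEL (-0.49) and ERMAP (-0.44), and tropomodulin, TMOD1, rose (0.45 ± 0.09). Of 21 erythroid and globin regulators, 9 fell and 0 rose, 10 and 0 adjusted over the list alone (camera adjusted p = 0.000203, adjusted p = 0.146 with an estimated correlation), among them BCL11A, the erythropoietin receptor EPOR (-0.5 ± 0.07), its kinase JAK2 (-0.65 ± 0.11) and the cofactor LDB1 (-0.38). Of 20 genes of late maturation, 6 fell and 1 rose, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.156 with an estimated correlation). The peroxide-removing enzyme PRDX2 fell (-0.58 ± 0.08), as did OSBP2 (-0.46), and the carbonic anhydrase CA2 rose (0.41 ± 0.07). The named members each lay beyond luciferase in 5 of 5 arrays.

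Markers of other blood lineages were higher. Of 23 granulocyte and monocyte genes, 9 rose and 0 fell, as many adjusted over the list alone (camera adjusted p = 0.000395, adjusted p = 0.24 with an estimated correlation), led by the granule proteins MPO (1.19 ± 0.15), CTSG (1.08 ± 0.23) and ELANE (0.86 ± 0.13). Of 13 mast cell, basophil and eosinophil genes, 6 rose and 0 fell, 7 and 0 adjusted over the list alone (camera adjusted p = 7.26e-05, adjusted p = 0.156 with an estimated correlation), such as the prostaglandin D synthase HPGDS (1.04 ± 0.12), MS4A3 (0.79 ± 0.07) and the tryptase TPSAB1 (0.64). Of 18 megakaryocyte and platelet genes, 4 rose and 0 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.00733, adjusted p = 0.156 with an estimated correlation), with the integrin chains ITGB3 (1.71 ± 0.12) and ITGA2B (0.65) and the tetraspanin CD9 (0.96 ± 0.11). That list was lost without A3 replicate 3 (adjusted p = 0.0681). Each named marker lay above luciferase in 5 of 5 arrays. Of 19 stem and progenitor genes, 2 rose and 0 fell, as many adjusted over the list alone, namely GATA2 (0.48) and KIT (0.42), and the list did not pass (camera adjusted p = 0.236). Without luciferase replicate 3, in which the progenitor genes SPINK2, PROM1 and FLT3, singled out after their values were seen, read 3.51, 2.51 and 2.08 above the other luciferase arrays, it passed (0.000351). Of 19 lymphoid genes, 2 rose and 1 fell, as many adjusted over the list alone, with NKG7, a protein of cytotoxic granules, at 0.78 and the interleukin receptor chain IL2RB at 0.53 (camera adjusted p = 0.284).

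Of 17 cholesterol synthesis genes, 13 rose and 0 fell, 14 and 0 adjusted over the list alone (camera adjusted p = 9.18e-13, adjusted p = 0.0498 with an estimated correlation). MSMO1 (0.73 ± 0.06), SQLE (0.7 ± 0.06), DHCR7 (0.69 ± 0.11) and HMGCS1 (0.57 ± 0.06), all enzymes of the pathway, lay above luciferase in 5 of 5 arrays. Immediate early and heat shock genes were higher, with 5 of 18 up and 0 down, 6 and 0 adjusted over the list alone (camera adjusted p = 0.00094, adjusted p = 0.24 with an estimated correlation). EGR1 (1.48 ± 0.1), IER3 (1.48 ± 0.11) and BTG1 (0.76 ± 0.09), genes that respond quickly to signals, rose in 5 of 5 arrays. Of 19 genes of the unfolded protein and amino acid stress response, 3 rose and 2 fell, 4 and 2 adjusted over the list alone (camera adjusted p = 0.0431, adjusted p = 0.24 with an estimated correlation). DDIT3, a factor induced by such stress, rose (0.6 ± 0.09) and ASNS, which makes asparagine and is induced when amino acids are short, fell (-0.59 ± 0.13). The list was lost without luciferase replicate 1 (0.152), luciferase replicate 2 (0.0853) or A3 replicate 1 (0.0554). The call came from A3, with 8 members higher and 0 lower with A3 (mean 0.273, camera adjusted p = 0.000247, adjusted p = 0.129 with an estimated correlation) and 1 higher and 3 lower with G10, where the list did not pass (mean -0.088, camera adjusted p = 0.287). Of 27 interferon response genes, 2 rose and 2 fell, as many adjusted over the list alone, with RSAD2 at 1.3 and IFI27 at -1.06, both antiviral or interferon-induced (camera adjusted p = 0.308).

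Of 23 genes of G1/S and DNA replication, 4 fell and 0 rose, 9 and 0 adjusted over the list alone (camera adjusted p = 7.26e-05, adjusted p = 0.156 with an estimated correlation), most of all cyclin E, CCNE1 (-0.59 ± 0.07, 5 of 5 arrays). Of 22 genes of G2/M and mitosis, 3 fell and 0 rose, as many adjusted over the list alone (camera adjusted p = 0.00261, adjusted p = 0.24 with an estimated correlation). Of 7 CDK inhibitors, 2 rose and 0 fell, as many adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.156 with an estimated correlation), namely CDKN1A, the p21 inhibitor (0.9 ± 0.13, 5 of 5 arrays), and CDKN1C (0.75 ± 0.09, 5 of 5). Its call was lost without luciferase replicate 1 (0.0528) or G10 replicate 3 (0.0523), and in lists without shared genes (0.121). Of 19 p53 targets, 2 rose and 5 fell, 2 and 6 adjusted over the list alone (camera adjusted p = 0.0371, adjusted p = 0.156 with an estimated correlation), and the list was lost without luciferase replicate 1 (0.0648) or with arrays centred on their medians (0.0564). CDKN1A and TP53I3 (0.52 ± 0.09) rose, and the death receptor TNFRSF10B (-0.62 ± 0.06) and SESN1 (-0.4 ± 0.05) fell, each in 5 of 5 arrays. Of 18 genes of MYC and ribosome biogenesis, 2 fell and 0 rose, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0442, adjusted p = 0.257 with an estimated correlation). The list call was lost without luciferase replicate 1 (0.19), luciferase replicate 2 (0.114), A3 replicate 3 (0.07), G10 replicate 1 (0.0589) or G10 replicate 3 (0.0523).

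Of 15 histone deacetylases, HDAC1 itself and HDAC7 (-0.59 ± 0.1) fell and HDAC5 rose (0.5 ± 0.09), as many adjusted over the list alone (camera adjusted p = 0.0442, adjusted p = 0.156 with an estimated correlation). The list holds HDAC1, the target of the hairpins, so part of its downward call was set by the design. The list was lost without luciferase replicate 1 (0.0685), luciferase replicate 3 (0.0721), A3 replicate 3 (0.0558) or G10 replicate 3 (0.0785), and with arrays centred on their medians (0.0564). Of 23 partners of these enzymes in the SIN3, NuRD and CoREST complexes, 1 rose and 1 fell, as many adjusted over the list alone (camera adjusted p = 0.543). Of 11 linker, variant and polyadenylated histone genes, 2 rose and 0 fell, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0442, adjusted p = 0.299 with an estimated correlation), with H2BC5 at 0.6 ± 0.13. That list was lost without luciferase replicate 1 (0.152), luciferase replicate 2 (0.167), A3 replicate 1 (0.0826) or G10 replicate 2 (0.091). Of 21 neuronal genes repressed through REST, the sodium channel SCN3A alone rose (1.29 ± 0.17), also adjusted over the list alone (camera adjusted p = 0.274).

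Of the 23 lists, 17 passed camera for HDAC1, 8 higher and 9 lower, but only heme synthesis and cholesterol synthesis held with an estimated correlation, and fry called 17. Leaving out the dimmest genes ended the calls of the membrane (0.0564), histone deacetylase (0.0733), CDK inhibitor (0.0733), p53 (0.061), unfolded protein (0.0746), MYC (0.0733) and histone gene (0.0918) lists. Pooled hairpins ended those of the CDK inhibitor (0.112), p53 (0.123), unfolded protein (0.189) and histone gene (0.0895) lists. Histone deacetylases were also lost with array weights (0.0571), only the groups compared (0.0524) and luciferase replicate 3 and H6 replicate 3 both out (0.076). MYC genes were lost with only the groups compared (0.0519), and histone genes with the mean of all probe sets (0.119) and in fry (0.056). Stem and progenitor genes passed with array weights (0.027) and with luciferase replicate 3 and H6 replicate 3 both out (0.000609). Among genes called with A3 and with G10, which share the luciferase arrays, 422 rose with both, 197 fell with both and 52 had opposite signs, against 70.4 and 35.8 for independent lists. Over all genes r was 0.568 and the covariance 0.0575, against 0.446 and 0.00792 for simulated unchanged groups, and part of the overlap may come from the shared controls. With the hairpins pooled, so that their difference counted as spread, 535 genes passed, and the calls of CDKN1A (adjusted p = 0.41), ALDH1A2 (0.0973), SEPTIN10 (0.0758), CST7 (0.0726), ALAD (0.115) and JAK2 (0.194) were among those lost. Of the calls, 56.4% were higher, against 41.8% with arrays centred on their medians, and 1144 genes passed without luciferase replicate 2.

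The same questions were asked of HDAC2. HBE1 rose 2.9-fold, from 7.74 ± 0.29 (SD, n = 3) to 9.27 ± 0.46 (SD, n = 6), above luciferase in 6 of 6 arrays (log2 fold 1.53 ± 0.14, adjusted p = 8.03e-06). Its log2 fold was 1.16 with B10 and 1.9 with H6, although H6 lowered HDAC2 mRNA less. Gamma-globin, HBG1/HBG2, rose 1.12-fold, to 13.1 ± 0.06, in 6 of 6 arrays (0.16 ± 0.05, adjusted p = 0.0241). BCL11A fell 1.83-fold (-0.87 ± 0.09, adjusted p = 3.7e-05) and KLF1 1.23-fold (-0.3 ± 0.06, 0.00176), both in 6 of 6 arrays. GATA1, MYB and TAL1 did not pass, with -0.21, -0.01 and -0.09 and adjusted p-values of 0.116, 0.92 and 0.247.

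The gamma-globin call rested on single arrays and settings. It was lost without luciferase replicate 2 (adjusted p = 0.0983) or luciferase replicate 3 (0.072), with arrays centred on their medians (0.09, adjusted p = 0.219), with only the groups compared (0.0523) and with the hairpins pooled (0.0732), within a range of 0.000298 to 0.219 over 10 alternatives of which 6 passed. Of its other probe sets, the first rose (0.23, adjusted p = 0.00429) and the second did not pass (0.1, 0.194). Of the 7 globins, 2 rose and 3 fell, 3 and 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.917), with a median of -0.144 against a mean of 0.121 and an upward direction in camera. HBA1/HBA2 fell (-0.27 ± 0.08, adjusted p = 0.0339), but it read -0.73 with B10 and 0.18 with H6, lay below luciferase in 3 of 6 arrays and lost its call in 5 of 14 fits without 1 array (highest 0.157, without luciferase replicate 1). HBB fell (-0.14 ± 0.05, adjusted p = 0.0447, 4 of 6 arrays), at -0.27 with B10 and -0.02 with H6. It lost its call in 12 of those fits (0.159, without luciferase replicate 2). For HBA1/HBA2 and HBB, both calls were lost with quantile normalization (0.0683 and 0.0569), only the groups compared (0.0682 and 0.0934), and pooled hairpins (0.518 and 0.314). The replicate block (0.0563 and 0.0748) also ended them, as did luciferase replicate 3 and H6 replicate 3 both out (0.0646 and 0.1). HBB was lost with the mean of all probe sets too (0.0841). HBQ1 fell (-0.3 ± 0.08, adjusted p = 0.0203, 4 of 6 arrays), at -0.54 with B10 and -0.07 with H6. Its call was lost without luciferase replicate 2 (0.129) and with pooled hairpins (0.242). HBD and HBZ did not pass (0.15, adjusted p = 0.0807, and -0.27, 0.0799).

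In all, 2646 genes changed with the HDAC2 hairpins, 1437 higher and 1209 lower, and 172 by at least 2-fold, 157 higher and 15 lower. CALB1 (2.95 ± 0.15, adjusted p = 1.68e-07), the chemokine CCL2 (2.79 ± 0.15, 2.54e-07), HEPH (2.47 ± 0.12, 1.68e-07) and AXL (2.39 ± 0.2, 4.97e-06) rose most. SEPTIN10, ACP3, an acid phosphatase of the prostate, and EHD2 followed at 2.24, 2.18 and 2.12, then PTGS2, an inducible prostaglandin synthase (2.11 ± 0.14), albumin, ALB (2.02 ± 0.25), and the platelet integrin chain ITGB3 (1.92 ± 0.12). CCL2 and PTGS2 rose alike with both hairpins, by 2.81 and 2.78 and by 2.1 and 2.11, whereas ACP3 stood at 4.25 with B10 and 0.11 with H6. B3GALNT1 (-1.79 ± 0.17, adjusted p = 1.18e-05), the sodium pump subunit ATP1B2 (-1.69 ± 0.14, 4.35e-06), TUBB2B (-1.56 ± 0.21, 0.000171), SH3TC2 (-1.44) and TRIM10, a protein of erythroid maturation (-1.39 ± 0.14, 2.62e-05), fell most. DDN, the serine synthesis enzyme PSAT1, the transglutaminase TGM2, SELENOP and CYP21A2 fell by 1.31, 1.25, 1.2, 1.13 and 1.1. All 20 lay beyond luciferase in 6 of 6 arrays except ACP3, in 5.

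**Figure D3:**
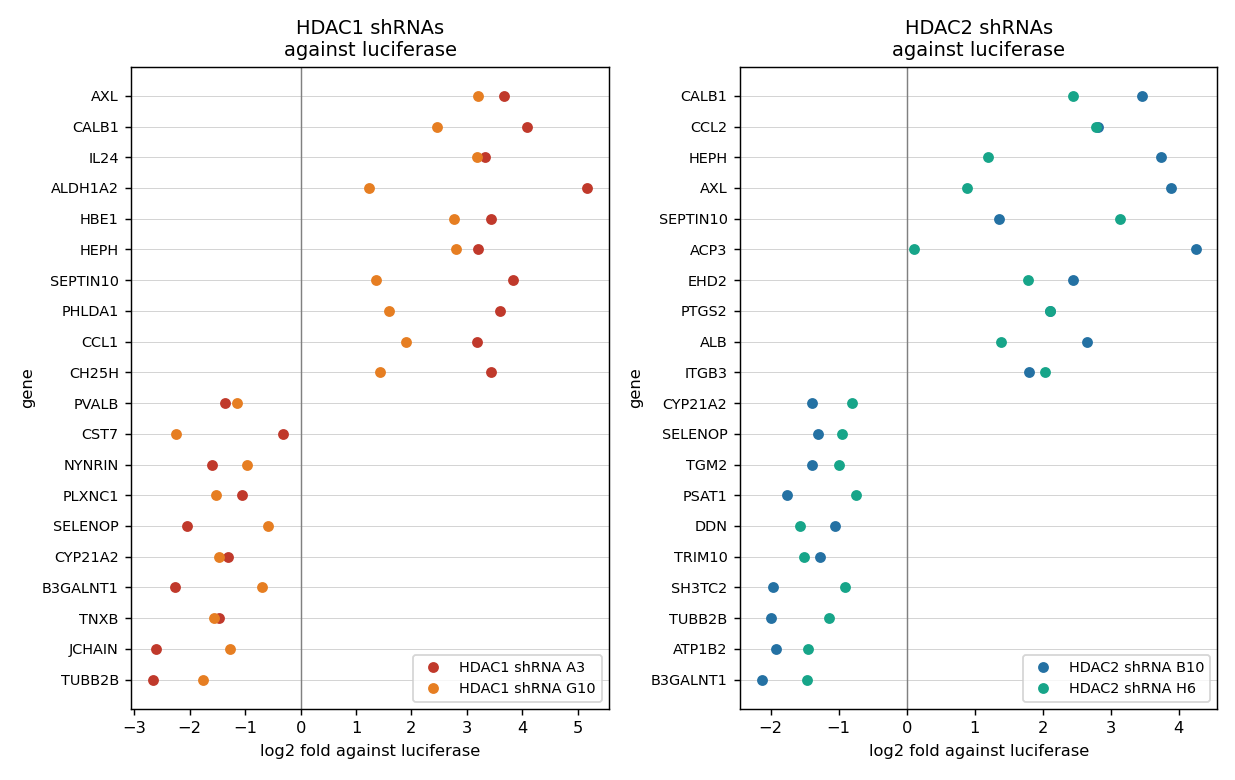
Log2 fold against luciferase of the genes with the largest rises and falls for HDAC1 or HDAC2 among those of 1 sign with both hairpins of the target, with 1 point per hairpin. The HDAC1 panel holds A3 and G10, and the HDAC2 panel B10 and H6. ACP3 runs from 0.11 with H6 to 4.25 with B10, and ALDH1A2 reaches 5.17 with A3, while HBE1 lies at 3.44 with A3 and 2.76 with G10.

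Erythroid lists were lower with the HDAC2 hairpins too. Of 13 genes of heme synthesis and iron uptake, 8 fell and 0 rose, 10 and 0 adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.015 with an estimated correlation), among them ALAD (-0.96 ± 0.09), the mitochondrial iron importer SLC25A37 (-0.79 ± 0.12) and UROS (-0.59). Of 19 membrane and blood group genes, 7 fell and 0 rose, 9 and 0 adjusted over the list alone (camera adjusted p = 0.000248, adjusted p = 0.0747 with an estimated correlation), such as ADD2 (-1.09 ± 0.09), KEL (-0.58) and the membrane skeleton protein EPB42 (-0.55). Of 21 regulators, 6 fell and 1 rose, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00191, adjusted p = 0.0903 with an estimated correlation), with EPOR at -0.5 ± 0.07 beside BCL11A and KLF1. Of 20 late maturation genes, 7 fell and 2 rose, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.167 with an estimated correlation), including OSBP2 (-0.68 ± 0.08) and PRDX2 (-0.67 ± 0.07). It was lost without luciferase replicate 2 (0.0807). The members named here lay below luciferase in 6 of 6 arrays.

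Markers of other lineages were higher with the HDAC2 hairpins as well. Of 18 megakaryocyte and platelet genes, 12 rose and 0 fell, 13 and 0 adjusted over the list alone (camera adjusted p = 4.99e-08, adjusted p = 0.0248 with an estimated correlation), such as ITGB3, the platelet chemokine PF4 (1.5 ± 0.24) and CD9 (1.11 ± 0.11), each in 6 of 6 arrays. Of 23 granulocyte and monocyte genes, 15 rose and 0 fell, 18 and 1 adjusted over the list alone (camera adjusted p = 4e-09, adjusted p = 0.0789 with an estimated correlation), with CTSG (1.5 ± 0.22, 5 of 6) and ELANE (1.08 ± 0.12, 6 of 6). Of 13 mast cell, basophil and eosinophil genes, 9 rose and 0 fell, as many adjusted over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.0747 with an estimated correlation), with HPGDS (1.27 ± 0.12), TPSAB1 (0.88 ± 0.08) and the IgE receptor chain FCER1A (0.87 ± 0.07) in 6 of 6 arrays. Of 19 stem and progenitor genes, 5 rose and 0 fell, as many adjusted over the list alone, with MEIS1 at 0.72 ± 0.12 and BCL2 at 0.49 ± 0.1, and the list did not pass (camera adjusted p = 0.0637). Without luciferase replicate 3 (3.82e-05) or with arrays centred on their medians (0.0292) it passed. So it did without both luciferase replicate 3 and H6 replicate 3 (5.18e-05) and with the replicate block (0.0452). Of 19 lymphoid genes, 2 rose and 1 fell, as many adjusted over the list alone, with NKG7 at 1.43 ± 0.13 (camera adjusted p = 0.658).

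Of 19 p53 targets, 8 rose and 0 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 4.36e-05, adjusted p = 0.015 with an estimated correlation). CDKN1A rose 2.67-fold (1.42 ± 0.12, adjusted p = 7.54e-06), TP53I3 by 0.61 and TNFRSF10B by 0.57, each in 6 of 6 arrays, though CDKN1A read 2.26 with H6 and 0.58 with B10. The list call came from H6, with 10 targets higher and 0 lower (mean 0.596, camera adjusted p = 2.33e-10, adjusted p = 0.000946 with an estimated correlation), while with B10 2 were higher and 4 lower (mean -0.04, camera adjusted p = 0.427). Of 7 CDK inhibitors, 3 rose and 1 fell, as many adjusted over the list alone (camera adjusted p = 0.0793), and the list passed without luciferase replicate 2 (0.0497). Of 23 genes of G1/S and DNA replication, 12 fell and 0 rose, 16 and 0 adjusted over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.0747 with an estimated correlation), such as CCNE1 (-0.62 ± 0.06), the helicase subunit MCM5 (-0.37 ± 0.07) and UNG (-0.3). Of 22 genes of G2/M and mitosis, 5 fell and 0 rose, as many adjusted over the list alone (camera adjusted p = 0.000136, adjusted p = 0.125 with an estimated correlation), with cyclin B1, CCNB1, at -0.22 ± 0.05. Of 18 genes of MYC and ribosome biogenesis, 11 fell and 0 rose, 16 and 0 adjusted over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.0414 with an estimated correlation), including UTP20 (-0.58 ± 0.08), RRS1 (-0.45) and MRTO4 (-0.32), all needed to build ribosomes. The members of the last 3 lists named here fell in 6 of 6 arrays.

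Of 17 cholesterol synthesis genes, 9 rose and 0 fell, 12 and 0 adjusted over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.0789 with an estimated correlation), with MSMO1 (0.57 ± 0.05), HMGCS1 (0.5 ± 0.05) and IDI1 (0.45) in 6 of 6 arrays. Of 19 genes of the unfolded protein and amino acid stress response, 10 rose and 2 fell, 11 and 3 adjusted over the list alone (camera adjusted p = 0.00159, adjusted p = 0.0903 with an estimated correlation). DDIT3 rose (0.73 ± 0.08) and ASNS fell (-0.8 ± 0.12), as with HDAC1. Of 18 immediate early and heat shock genes, 4 rose and 0 fell, as many adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.461 with an estimated correlation), led by EGR1 (1.28 ± 0.09) and IER3 (1.18 ± 0.1). The call was lost without luciferase replicate 1 (0.236), luciferase replicate 2 (0.0884), B10 replicate 2 (0.0671) or H6 replicate 3 (0.0556). Of 27 interferon response genes, 3 rose and 1 fell, as many adjusted over the list alone, with RSAD2 at 0.99 ± 0.12 and IFI27 at -1.06 ± 0.23 (camera adjusted p = 0.083), and the list passed without G10 replicate 2 (0.046) or B10 replicate 1 (0.0281) and with arrays centred on their medians (0.0315).

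Of 15 histone deacetylases, HDAC2 itself, HDAC7 (-0.42 ± 0.09) and HDAC1 fell and 0 rose, 5 and 0 adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.0903 with an estimated correlation). As that list holds HDAC2, the target of the hairpins, part of its downward call was set by the design. Of 23 partners in the SIN3, NuRD and CoREST complexes, 3 rose and 4 fell, as many adjusted over the list alone, with the corepressor RCOR1 at -0.3 ± 0.06 (camera adjusted p = 0.414). Of 11 histone genes, 4 rose and 0 fell, as many adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.244 with an estimated correlation), led by H2AC6 (1 ± 0.17), which read 1.92 with H6 and 0.07 with B10. That list was lost without luciferase replicate 1 (0.0656) or luciferase replicate 2 (0.0754). Of 21 neuronal genes, 2 rose and 0 fell, while 0 passed adjusted over the list alone, and the median of -0.019 was opposite in sign to the mean of 0.056 (camera adjusted p = 0.806). UCHL1, a neuronal ubiquitin hydrolase, read 1.03 ± 0.29, and 0.685 without luciferase replicate 2. Its call was lost without luciferase replicate 1 (0.1) or luciferase replicate 2 (0.141), and with pooled hairpins (0.411).

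Of the 23 lists, 16 passed camera for HDAC2, 8 higher and 8 lower, of which heme synthesis, megakaryocyte, p53 and MYC lists held with an estimated correlation, and fry called 18. Late maturation was lost with the mean of all probe sets (0.0572), immediate early genes with the dimmest genes left out (0.0784) and with that mean (0.0781), and histone genes with the dimmest genes left out (0.0582) and pooled hairpins (0.0543). Stem and progenitor genes passed with the dimmest genes left out (0.00633) and array weights (0.00604), and fry called the complex partners (0.0289) and CDK inhibitors (0.000538). Among genes called with B10 and with H6, which share the luciferase arrays, 660 rose with both, 388 fell with both and 100 had opposite signs, against 147.9 and 110.5 for independent lists. Over all genes r was 0.536 and the covariance 0.0575, against 0.5 and 0.00793 in the simulation, and here too part of the overlap may come from the shared controls. With the hairpins pooled, 1082 genes passed, and calls lost included CDKN1A (adjusted p = 0.0603), AXL (0.0546), SEPTIN10 (0.0535), ACP3 (0.184) and H2AC6 (0.223). Of the calls, 54.3% were higher, against 32.6% with arrays centred on their medians, and 1744 and 1710 genes passed without luciferase replicate 1 or luciferase replicate 2.

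**Figure D4:**
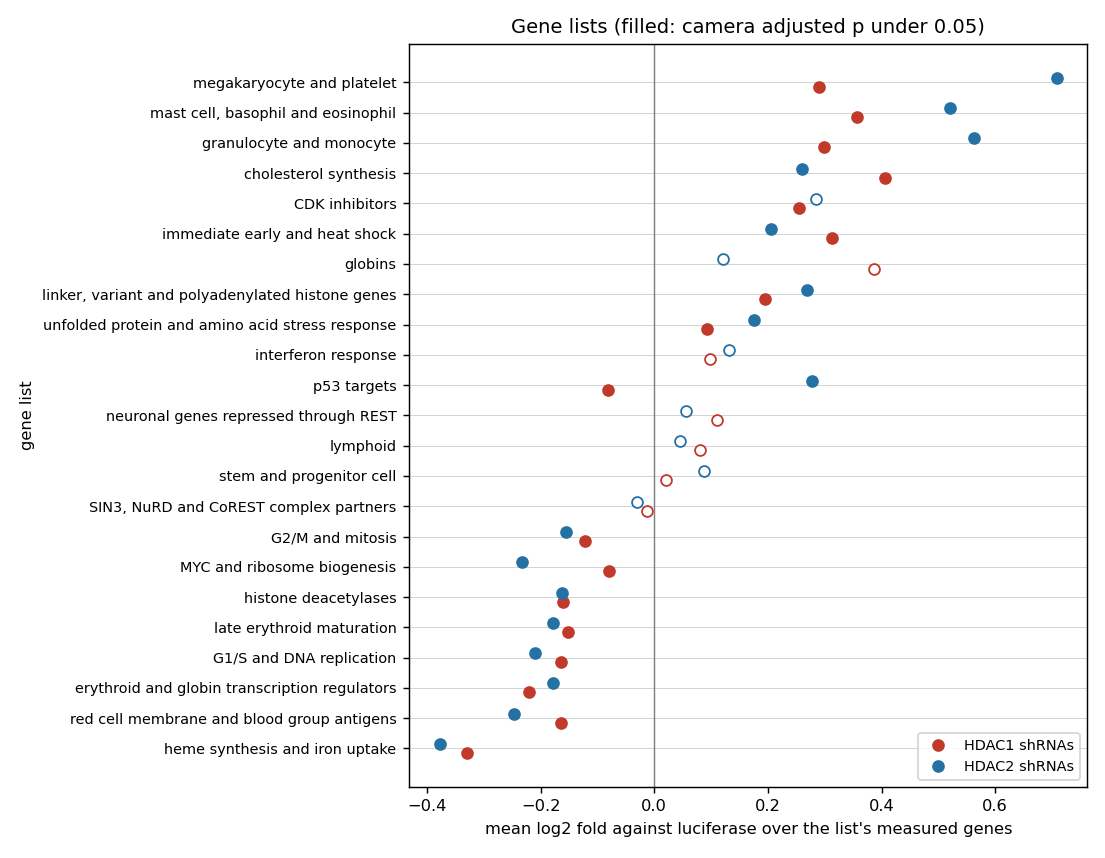
Mean log2 fold of the measured members of each of the 23 gene lists for the HDAC1 hairpins (red) and the HDAC2 hairpins (blue) against luciferase, with filled points where camera gave an adjusted p under 0.05. Cholesterol synthesis lies at 0.406 and 0.26, heme synthesis at -0.329 and -0.377, and p53 targets at -0.082 and 0.278.

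The direct comparison of the HDAC1 with the HDAC2 hairpins asked where the effects differed. Each target was lowest with its own hairpins, with HDAC1 at -0.96 ± 0.06 (adjusted p = 4.75e-07) and HDAC2 at 0.71 ± 0.05 (1.9e-06). HBE1 was 2.97-fold higher with the HDAC1 hairpins (1.57 ± 0.12, adjusted p = 3.65e-06, 5 of 5 arrays above all 6 HDAC2 arrays). HBG1/HBG2, BCL11A, KLF1 and TAL1 did not differ past the threshold, at -0.01, -0.12, 0.02 and 0.14 (adjusted p = 0.907, 0.436, 0.837 and 0.0758), nor did GATA1 (0.03, 0.891) or MYB (-0.03, 0.783). The p53 targets were lower with the HDAC1 hairpins, with 13 of 19 lower and 0 higher, as many adjusted over the list alone (camera adjusted p = 3.15e-12, adjusted p = 0.000486 with an estimated correlation). This difference rested on H6: the list means against luciferase were -0.075 with A3, -0.089 with G10, -0.04 with B10 and 0.596 with H6. TNFRSF10B (-1.19 ± 0.05) and SESN1 (-0.86 ± 0.04) differed in 5 of 5 arrays, and CDKN1A (-0.52 ± 0.11, adjusted p = 0.00645) in 0 of 5, with its highest means at 2.26 for H6 and 1.33 for A3 against luciferase.

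In this comparison 1502 genes differed, 718 higher and 784 lower with the HDAC1 hairpins, 59 of them by at least 2-fold, 24 higher and 35 lower. ALDH1A2 (2.45 ± 0.23, adjusted p = 2.94e-05, 3 of 5 arrays), CH25H (2.03 ± 0.19, 2.74e-05, 5 of 5), IL24 (1.75 ± 0.35, 0.00487, 2 of 5), SAMD4A, an RNA-binding repressor of translation (1.59 ± 0.12, 3.86e-06, 5 of 5), and HBE1 were highest. CST7, a cystatin of immune cells (-2.03 ± 0.07, adjusted p = 4.61e-09), NYNRIN (-1.82 ± 0.09, 9.5e-08), the semaphorin receptor PLXNC1 (-1.59 ± 0.08, 1.43e-07), CKAP4 (-1.58 ± 0.09, 2.1e-07) and the mitochondrial carrier SLC25A24 (-1.38 ± 0.16, 0.000127) were lowest, each in 5 of 5 arrays. CKAP4 stood below luciferase with A3 and G10 (-0.98 and -0.7) and above it with B10 and H6 (0.59 and 0.89). With the hairpins pooled, 333 genes differed, and ALDH1A2 (adjusted p = 0.168), SLC25A24 (0.0572) and CDKN1A (0.487) did not pass. The globins HBA1/HBA2, HBB, HBD, HBQ1 and HBZ did not pass, at -0.02, -0.03, 0.06, 0.06 and 0.21 (adjusted p = 0.922, 0.735, 0.503, 0.662 and 0.152).

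Beside p53 targets, 5 of the 23 lists passed. Lower with the HDAC1 hairpins were 8 of 18 megakaryocyte and platelet genes with 0 higher, as many adjusted over the list alone (camera adjusted p = 5.02e-06, adjusted p = 0.0879 with an estimated correlation), such as GP1BA, a platelet receptor for von Willebrand factor (-0.82 ± 0.12, 5 of 5 arrays), and PF4 (-1 ± 0.21, 4 of 5), at -0.631 without A3 replicate 1 (adjusted p = 0.0148). Of 23 granulocyte and monocyte genes, 6 were lower and 0 higher, 11 and 0 adjusted over the list alone (camera adjusted p = 0.000216, adjusted p = 0.452 with an estimated correlation), with CD14 at -0.72 and CFD at -0.67. Of 13 mast cell, basophil and eosinophil genes, 3 were lower and 0 higher, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0251, adjusted p = 0.494 with an estimated correlation), with FCER1A at -0.45 ± 0.06, and the list was lost without A3 replicate 3 (0.0549), H6 replicate 3 (0.0592) or both luciferase replicate 3 and H6 replicate 3 (0.0502). Higher with the HDAC1 hairpins were 6 of 17 cholesterol synthesis genes with 0 lower, 8 and 0 adjusted over the list alone (camera adjusted p = 0.000112, adjusted p = 0.354 with an estimated correlation), such as SQLE (0.35 ± 0.05) and LSS (0.32). Of 18 genes of MYC and ribosome biogenesis, 6 were higher and 0 lower, 8 and 0 adjusted over the list alone (camera adjusted p = 3.7e-05, adjusted p = 0.0971 with an estimated correlation), with UTP20 at 0.36 and NOP16 at 0.31.

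The other 17 lists did not pass camera between the targets. With the members higher and lower given first, heme synthesis had 2 and 1 (adjusted p = 0.831), the membrane 3 and 1 (0.245), regulators 1 and 1 (0.329), late maturation 3 and 3 (0.579), stem and progenitor genes 0 and 3 (0.466) and lymphoid genes 2 and 1 (0.874). Globins had 1 and 0 (adjusted p = 0.211), histone deacetylases 4 and 2 (0.874), SIN3, NuRD and CoREST partners 1 and 0 (0.818), G1/S 3 and 0 (0.245), G2/M 0 and 0 (0.366) and CDK inhibitors 1 and 1 (0.976). Interferon genes had 0 and 2 (adjusted p = 0.466), the unfolded protein list 1 and 3 (0.0583), immediate early genes 2 and 0 (0.0572), histone genes 0 and 0 (0.536) and neuronal genes 3 and 0 (0.466). The median, mean and camera direction of histone deacetylases differed in sign (-0.001 and 0.002), as did those of CDK inhibitors, with a mean of -0.03 and an upward direction in camera. Immediate early genes passed without luciferase replicate 2 (0.0442), luciferase replicate 3 (0.0388), G10 replicate 2 (0.0347), B10 replicate 2 (0.0108) or both luciferase replicate 3 and H6 replicate 3 (0.0417), and with the mean of all probe sets (0.0156), a trended and robust prior (0.0307) and only the groups compared (0.0347). The unfolded protein list passed without A3 replicate 1 (0.0409), B10 replicate 3 (0.043) or H6 replicate 2 (0.0267), and with a trended and robust prior (0.0346), pooled hairpins (0.0143) and fry (0.042). Interferon genes passed without G10 replicate 2 (0.0347), and globins in fry (0.000911).

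The HDAC1 and HDAC2 effects resembled each other across genes. Their log2 folds correlated at r = 0.744 (rho = 0.674) over all genes, which are not independent replicates. Unchanged groups simulated against the same luciferase arrays gave r = 0.639, and the covariance was 0.0612 against 0.00793 in the simulation, a difference of 0.0533. Of the genes called in both comparisons, 733 rose in both and 433 fell in both, against 117 and 76.2 for independent lists, and 28 had opposite signs. Among those that rose in both by the rule for named genes were AXL, CALB1, HEPH and SEPTIN10, and TUBB2B, B3GALNT1, SELENOP and CYP21A2 fell in both. The luciferase arrays are too few to be split, so part of the excess can come from the shared controls.

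Each hairpin was also set against luciferase. A3 changed 1953 genes (1069 higher, 884 lower), led by ALDH1A2 (5.17 ± 0.35, adjusted p = 7.43e-07), CALB1 (4.09) and SEPTIN10 (3.84), with TUBB2B (-2.66), JCHAIN (-2.61) and the class II antigen HLA-DQA1 (-2.29) lowest. G10 changed 1292 (800 higher, 492 lower), led by AXL (3.2), IL24 (3.18) and HEPH (2.81), with CST7 (-2.25), TUBB2B (-1.77) and HDAC1 (-1.56) lowest. B10 changed 2327 (1328 higher, 999 lower), led by ACP3 (4.25 ± 0.11, adjusted p = 2.06e-10), AXL (3.89) and HEPH (3.74), with B3GALNT1 (-2.13), the adhesion molecule EPCAM (-1.99) and TUBB2B (-1.99) lowest. H6 changed 2696 (1353 higher, 1343 lower), led by the peptide gene NTS (3.78 ± 0.35, adjusted p = 1.15e-05), TNFAIP6 (3.29) and SEPTIN10 (3.14), with DDN (-1.57), pyruvate kinase PKLR (-1.53) and the protease MMP12 (-1.53) lowest. JCHAIN for A3 stood at -1.545 without luciferase replicate 3 (adjusted p = 0.00133). Its call was lost without A3 replicate 1 (0.126) or A3 replicate 3 (0.0914), with a trended and robust prior (0.0612) and with only the groups compared (0.147). That of MMP12 for H6 was lost without luciferase replicate 1 (0.0542), luciferase replicate 2 (0.085), H6 replicate 2 (0.0688) or H6 replicate 3 (0.0747). With arrays centred on their medians the share of higher calls moved from 54.7% to 44.4% for A3, 61.9% to 43.8% for G10, 57.1% to 35.7% for B10 and 50.2% to 34% for H6. Without A3 replicate 1, A3 changed 1071 genes, and the remaining A3 array was then assumed to vary like the other groups.

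The hairpins of a target differed from each other in many genes. A3 and G10 differed in 1627, 814 higher and 813 lower with A3, and 221 of these by at least 2-fold. B10 and H6 differed in 2354, 1256 higher and 1098 lower with B10. HBE1 was higher with A3 than with G10 (0.68, adjusted p = 0.0205), a call lost without A3 replicate 1 (0.118), A3 replicate 3 (0.0906) or G10 replicate 2 (0.064), and it was lower with B10 than with H6 (-0.74, 0.00507). Also lower with B10 than with H6 were HBA1/HBA2 at -0.91 (adjusted p = 3.42e-05), HBD at -0.71 (1.17e-05), HBQ1 at -0.46 (0.00469) and HBB at -0.25 (0.00611), and the list of globins passed with 5 of 7 lower and 0 higher, as many adjusted over the list alone (camera adjusted p = 1.71e-05, adjusted p = 0.009 with an estimated correlation). CDKN1A was lower with B10 than with H6 by a log2 fold of -1.67 ± 0.14 (adjusted p = 6.17e-06), and 14 of 19 p53 targets were lower with 0 higher, 15 and 0 adjusted over the list alone (camera adjusted p = 1.68e-13, adjusted p = 0.000325 with an estimated correlation). Against luciferase, 10 p53 targets rose with H6 and 0 fell (camera adjusted p = 2.33e-10, adjusted p = 0.000946 with an estimated correlation), while with B10 2 rose and 4 fell (camera adjusted p = 0.427). In H6 replicate 3, epithelial transcripts such as KRT18, KRT8 and TFF1, singled out after their values were seen, read 4.85, 4.52 and 6.37 above the other H6 arrays. A3 and G10 differed in 694 genes without A3 replicate 1.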

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

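The tests of the 3 patterns weighed in this part were all chosen after the patterns had been seen, while the counts over other splits of the arrays and the differences between groups were planned.

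In HDAC2 H6 replicate 3, 37 genes read over 2 log2 units above the other H6 arrays and 0 below, and in luciferase replicate 3 12 genes did and 0 below. Epithelial transcripts led in the first array, with GATA3 6.86, TFF1 6.37, KRT18 4.85, KRT8 4.52 and KRT19 4.23 above its mates, and recurred in the second beside TSC22D3, SPINK2 and JCHAIN, with GATA3 at 3.39, KRT18 at 2.95 and TFF1 at 2.78. An effect of the hairpin is argued against, because 25 luminal breast epithelial markers, of which 4 are brighter than the median gene in the other arrays, had a median of -0.01 in the other H6 arrays against luciferase. RNA of such epithelial cells is a candidate source for H6 replicate 3. There 50% of the 12 markers not used to notice the pattern lay over 0.5 above the mates. In lists of 4 other cell types at most 5% did, although ESR1 of the epithelial list stood at only 0.06. The CD34 selection of the starting cells should remove epithelial cells, but its purity, and when or how such RNA entered, were not tested. For luciferase replicate 3, 0% of those 12 markers lay over 0.5 above the mates, against up to 25% in a comparison list. But that array holds only 0.063 of the excess of H6 replicate 3, the median over 13 bright markers, which ran from 0.014 to 0.19. At the median alone a prediction was made, of 0 markers, a calculation added after the result was seen. In that array this source and others cannot be told apart.

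The p53 targets were higher with H6 than with B10, by a mean log2 fold of -0.64 for B10 minus H6. A deeper knockdown of HDAC2 mRNA is argued against, because B10 lowered that mRNA more and yet had the lower p53 targets (-0.636 before rounding). Both orders were known before this test, and HDAC2 protein was not measured. The foreign transcripts of H6 replicate 3 are argued against too, because without that array the list still passed with an estimated correlation (adjusted p = 0.000965). For a true effect that grows with loss of HDAC2 mRNA, the same values apply and are not a further test. HDAC2 was lower with B10 than with H6 (-0.33 ± 0.07, limma adjusted p = 0.00395), but the list means were -0.04 and 0.596. Sequence and depth differ together between these hairpins, so they cannot settle such a relation. An effect of the H6 sequence on other transcripts, or a difference in infection, may each account for the pattern, and neither was tested.

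Lists of granulocyte, megakaryocyte and mast cell markers passed upward with both targets at the preset correlation, but with an estimated correlation the adjusted p-values were 0.24, 0.156 and 0.156 for HDAC1 and 0.0789, 0.0248 and 0.0747 for HDAC2. A lower share of erythroid cells alone would raise bright markers of other types alike only if erythroid cells lacked them and signals were uncompressed. The 17 members brighter than 9 on the log2 scale moved apart. For HDAC1 their SD of 0.39 was 4.32 times their median SE (from PPBP at -0.34 ± 0.33 to MPO at 1.19 ± 0.15). For HDAC2 the SD of 0.3 was 3.38 times that SE (from RUNX1 at -0.03 to PPBP at 0.99). Whether erythroid cells lack these transcripts was not tested, and CLC and RNASE2 read 12.25 and 11.96 in luciferase arrays, so the spread cannot decide. The arrays with epithelial transcripts are argued against, because without both of them all 3 lists still passed for each target at that preset correlation, the only one used in this test. A lower share of erythroid cells, a change in which of these cell types were present, and a change in regulation within erythroid cells may each contribute. All stay open, since no test here separates them.

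The direct test of HDAC1 against HDAC2 hairpins singled out HDAC1 itself (-0.96), HDAC2 itself (0.71), HBE1 (1.57), CDKN1A (-0.52), ALDH1A2 (2.45), CH25H (2.03), IL24 (1.75) and SAMD4A (1.59). It also singled out CST7 (-2.03), NYNRIN (-1.82), PLXNC1 (-1.59), CKAP4 (-1.58) and SLC25A24 (-1.38). Lists that differed between the targets were granulocyte and monocyte (mean -0.26), megakaryocyte and platelet (-0.42), mast cell, basophil and eosinophil (-0.16), p53 targets (-0.36), cholesterol synthesis (0.15) and MYC and ribosome biogenesis (0.15). With an estimated correlation the p53 list alone held, and it rested on H6, with means against luciferase of 0.596 for H6, -0.04 for B10, -0.075 for A3 and -0.089 for G10.

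Between A3 and G10, 4 lists differed, and 0 held with an estimated correlation. Of 27 interferon response genes, 7 were lower with A3 and 0 higher, 9 and 0 adjusted over the list alone (mean -0.35, camera adjusted p = 0.000812, adjusted p = 0.622 with an estimated correlation). Of 19 genes of the unfolded protein and amino acid stress response, 8 were higher and 0 lower, 10 and 0 adjusted over the list alone (0.36, 1.36e-06, adjusted p = 0.0881 with an estimated correlation). MYC and ribosome biogenesis genes had a mean of 0.13 (3 of 18 higher, camera adjusted p = 0.0271) and immediate early and heat shock genes of 0.26 (5 of 18 higher, camera adjusted p = 0.0124), each with adjusted p = 0.622 with an estimated correlation.

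Between B10 and H6, globins (mean -0.48), p53 targets (-0.64), G1/S and DNA replication genes (0.14) and MYC and ribosome biogenesis genes (0.15) differed. Of 23 G1/S genes 9 were higher with B10 and 1 lower, and of 18 MYC genes 6 were higher and 1 lower (camera adjusted p = 0.029 for each, adjusted p = 0.469 with an estimated correlation). Among the 1923 probe sets without a gene name, 108 were higher and 75 lower with the HDAC1 hairpins, or 9.5% called, against 12.6% of the other probe sets when each probe set is tested by itself. With the HDAC2 hairpins 124 were higher and 121 lower, or 12.7% against 19% of the other probe sets.

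Other splits of the same arrays were fitted as 2 groups, with all arrays taken as exchangeable although they come in hairpin groups, of which there are too few to regroup whole. For HDAC1 against luciferase, 1 of 56 splits, the real one with 553 genes, called as many, and the highest other called 219. No other grouping of single arrays called as many, but arrays of 1 hairpin resemble each other, so splits that keep hairpins whole are favoured. For whole hairpins chance cannot be excluded, because there are too few to regroup. The split that called 219 was luciferase and A3 against G10. For the lists of HDAC1 against luciferase, 1 of 56 splits called as many as the real 16, but with 15 in the highest other this count is weak evidence against chance. For HDAC2 against luciferase, 1 of 84 splits, the real one, called as many as the real 1101 genes. Chance cannot be excluded for a grouping of whole hairpins. The split of luciferase and B10 against H6 called 1099, which points to a structure set by the H6 arrays. For its lists, 4 of 84 splits called as many as the real 15, with 16 in the highest other, so this count does not exclude chance. For HDAC1 against HDAC2, 2 of 100 splits drawn, the real one among them, called as many as the real 244 genes. Here too chance cannot be excluded for whole hairpins. The split of A3 and B10 against G10 and H6 called 493, a structure that follows the hairpins and not the target. For its lists, 11 of 100 splits called as many as the real 7, with 11 in the highest other, and chance cannot be excluded. In these 3 comparisons 50 of the other 55, 72 of 83 and 83 of 99 splits called at least 1 list, so the preset correlation calls lists for arbitrary splits too. With 3 arrays against 3, the 10 splits are too few for a share under 0.05: G10, B10 and H6 against luciferase called 1000, 1866 and 1956 genes and B10 against H6 1944, with 1 split as large and 0 in the highest other for each.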

How the results depend on the processing

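The fit without luciferase replicate 3 and H6 replicate 3 was chosen after seeing the data, and all other alternatives were planned. HDAC1 in its own arrays and HDAC2 in its own kept direction and side of the threshold in every alternative, with adjusted p-values of 5.55e-10 to 0.000703 and 2.37e-09 to 0.000306. Gamma-globin did not. For HDAC2 it lost its call with arrays centred on the median (0.088, adjusted p = 0.219), only the groups compared (0.158, 0.0523), pooled hairpins (0.158, 0.0732) and luciferase replicate 3 and H6 replicate 3 both out (0.145, 0.0966). For HDAC1 it passed with the lower part of the genes left out (0.146, 0.0284), the mean of all probe sets (0.18, 0.0107) and a trended and robust prior (0.146, 0.00116). The ranges over alternatives were 0.000298 to 0.219 and 0.00116 to 0.255. Leaving out dim genes left 10 lists for HDAC1, and an estimated correlation left 2, 4 and 1 for HDAC1, HDAC2 and their difference. Each probe set by itself, a larger number of tests, gave 2733, 4081, 3016, 1987, 3538 and 4263 for HDAC1, HDAC2, A3, G10, B10 and H6 and 3720 for B10 against H6. Only the groups compared gave 1253 for A3. Pooled hairpins, whose difference then counts as spread, gave 535, 1082 and 333. A log2 fold of at least 1, by construction, left 183, 172 and 59 genes, 314, 151, 199 and 262 for the single hairpins, and 221 and 181 for the hairpin pairs. Spearman correlation of the profiles was 0.674. HBZ with H6 reversed with the mean of all probe sets (0.443, adjusted p = 0.0434), by construction, because its probe sets differ in sign. Tested by itself, the probe set used gave -0.16 (limma adjusted p = 0.389). The other gave 1.05 (0.00635) and is dim, at 3.94 in luciferase arrays. Where construction is not named, the cause was not tested.

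Without 1 array, counts ran from 1144 to 1791 for HDAC1, 1710 to 2713 for HDAC2, 1071 to 2072 for A3 and 694 to 1747 for A3 against G10, lists for HDAC1 from 11 to 17, and gamma-globin for HDAC2 from 0.145 to 0.181. The lowest were without luciferase replicate 2 for HDAC1 and HDAC2, and without A3 replicate 1, which leaves a lone A3 array assumed to vary like the other groups, for A3 and A3 against G10. The lists fell to 11 without luciferase replicate 1, and gamma-globin to 0.145 without luciferase replicate 3. Without luciferase replicate 3 and H6 replicate 3, HDAC1, HDAC2 and their difference gave 1891, 2641 and 1612 genes. Of named gene results in the fits without 1 array, 5483 kept their side of the threshold, 457 lost their call and 10 gained one, and of list results 924, 29 and 13. A change of direction was counted only where a fit passed. Of named gene results under the other alternatives, 3782 kept their side of the threshold, 282 lost their call, 45 gained one and 1 reversed. Of list results, 820 kept theirs, 58 lost and 19 gained a call. The replicate numbers do not pair the samples: of 26 same-numbered pairs 5 had a correlation of deviations over 0.1 (range -0.201 to 0.184), and 3 of 14 arrays were closest to their own number. The replicate block gave 1592, 2474 and 1351 genes, gamma-globin at 0.148 (adjusted p = 0.09) and 0.158 (0.0436), and 17, 17 and 6 lists. Intensities near the floor and ceiling of the scale limit what very dim and very bright genes, gamma-globin among them, can show.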

Other observations

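The test of the hypothesis in this part was chosen after the profiles had been seen.

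Some genes differed strongly between the hairpins of a target, named here by the rule for hairpin pairs. MMP1, a collagenase, rose with A3 to 7.34 ± 0.11 (SD, n = 2) and stood at 3.69 ± 0.12 (n = 3) with G10 and 3.71 ± 0.07 (n = 3) in luciferase, a difference between the hairpins of 3.66 ± 0.12 (SE, adjusted p = 2.02e-09, 2 of 2 A3 arrays). ENTPD3, an enzyme that degrades extracellular nucleotides, differed likewise (3.14 ± 0.2, adjusted p = 5.62e-07), as did ALDH1A2 (3.94 ± 0.35, 1.25e-05). Higher with G10 were CD1A, an antigen-presenting molecule of dendritic cells (-2.61 ± 0.12, adjusted p = 7.37e-08), S100B (-2.81 ± 0.28, 2.48e-05) and the class II antigen HLA-DQA1 (-2.67 ± 0.18, 9.4e-07). CD1A read 6.48 ± 0.05 with G10 and 4.01 ± 0.21 in luciferase, while HLA-DQA1 read 6.21 ± 0.2 with A3 and 8.5 ± 0.13 in luciferase.

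Between the HDAC2 hairpins, ACP3 (4.14 ± 0.11, adjusted p = 2.85e-10), the epithelial gene TRIM29 (3.22 ± 0.21, 8.12e-07) and AXL (3 ± 0.23, 2.79e-06) were higher with B10 in 3 of 3 arrays. The neurotensin gene NTS (-4.05 ± 0.35, adjusted p = 7.19e-06), the Notch target HEY1 (-3.47 ± 0.19, 2.76e-07) and TNFAIP6, induced by inflammation (-3.24 ± 0.21, 7.44e-07), were higher with H6 in 3 of 3. These 3 genes were also higher with both HDAC1 hairpins than with luciferase, with log2 folds of 2.82 and 1.69 for NTS, 2.69 and 1.77 for HEY1, and 3.2 and 1.64 for TNFAIP6 with A3 and G10, and stood at -0.27, -0.64 and 0.06 with B10.

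If the profiles followed the target, hairpins of 1 target would resemble each other more than hairpins of different targets. After correction for the shared luciferase arrays, the correlation across genes was 0.598 for A3 and G10 and 0.543 for B10 and H6. Across targets it was 0.661 for A3 and B10, 0.582 for A3 and H6, 0.652 for G10 and B10 and 0.502 for G10 and H6. The mean within targets minus that across targets was -0.029, and between -0.04 and -0.016 without each array in turn. The prediction was not met by these hairpins, but leaving out arrays does not measure the spread between hairpins. The pairs across targets alone ran from 0.502 to 0.661, so the difference cannot decide whether profiles follow the target.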
